A study of Rattus norvegicus with 6 samples.

How the data were processed

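Rat 3Y1 embryonic fibroblasts, stably transfected with an empty vector or with a vector for the cytoplasmic domain of MUC1, were profiled on 6 Affymetrix Rat Genome arrays. The groups were Vector in vitro, MUC1-CD in vitro and MUC1-CD in vivo (tumors under the skin of female athymic mice), with 2 arrays each that the labels call biological replicates. Each array was placed in its group by its own label. Per the labels, RNA of cultured cells was taken up in TRIzol, while tumors were snap-frozen, transferred to an RNA preservative, homogenized and put through columns as well as TRIzol, so the RNA preparation differs with the growth setting.

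The deposited values are MAS5 signals of each probe set, a microarray intensity on a linear scale, per the submitters' processing notes and the values themselves. The MAS5 version, its present and absent calls and any filter the authors applied are not given in the sources used here. The deposited intensity values had the same 2% trimmed mean on each array, and this scaling was kept. The table held 31099 probe sets, of which 57 were controls and were used only to describe the arrays. A platform annotation table listed 21262 probe sets: 20826 named a single gene, 436 named several and were left unnamed, and 9780 of the 31042 other than controls were not listed and are unnamed here. Symbols were updated through Entrez identifiers to the GRCr8 annotation, where 20758 matched. Chromosomes and neighbouring genes are those of GRCr8, and no coordinates are printed.

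Signals were transformed as log2(signal + 16). Probe sets with a mean signal over the 6 arrays at or above the 40th percentile (61.6) were kept (18625). All arrays entered 1 limma model with group as the only term (lmFit, then eBayes with a mean-variance trend), with 3 residual and a median of 3.70 prior degrees of freedom. P values are 2-sided and were adjusted by Benjamini-Hochberg over the kept probe sets, with a threshold of 0.05. A gene was represented by its kept probe set with the highest mean signal. Probe sets of 1 gene were called in opposite directions for 185 genes in MUC1-CD in vitro against Vector, 9 in tumors against MUC1-CD in vitro and 254 in tumors against Vector, and no gene named in the text was among them in the comparison it is named for. P values rest on the spread between arrays within groups, as 1 estimate shared by the 3 groups and moderated across probe sets. Vector replicates differed more than the others (SD of the difference 0.616 log2, against 0.257 in MUC1-CD culture and 0.284 in tumors). P values against Vector can therefore be too small, and those for tumors against MUC1-CD in vitro too large. No dates or batches were given in the sources used here.

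The comparisons, the test, its filter and pseudocount, the alternatives, the rule for named genes and 30 gene lists were fixed before the data were examined. Of these, 1 list is not reported here. The others cover MHC and antigen presentation, cholesterol synthesis, fatty acid and lipid synthesis, glycolysis, hypoxia targets, oxidative phosphorylation, cell cycle, p53 targets, MYC and ribosome biogenesis, collagens, matrix glycoproteins, matrix proteases, actin and smooth muscle, TGF-beta, WNT, NF-kB and MAPK targets, the unfolded protein response, NRF2 targets, complement and adhesion. The remaining lists hold markers of endothelium, macrophages, lymphoid cells and granulocytes, erythroid cells, skeletal muscle, adipocytes, keratinocytes, and pericytes and stroma. Each list with at least 5 measured members was tested with limma's camera at a preset correlation of 0.01, adjusted over 84 tests, beside camera with an estimated correlation and fry. With an estimated correlation, camera rests on the 3 residual degrees of freedom of the fit, so that test has little power here. Named genes are Muc1; the 10 largest rises and 10 largest falls of each step, among genes with adjusted p under 0.05 and no overlap between the arrays of both groups; the 5 largest each way for tumors against Vector and for genes changed the same way in both steps; and up to 4 members of each list with the smallest p.

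Calls shared by both steps were compared with independent lists of the same sizes, and the fold changes of both steps with 100 simulations of unchanged groups that shared the MUC1-CD in vitro arrays. The code was tested on simulated data with 200 changed probe sets of 18625, in 10 simulations per comparison. For MUC1-CD in vitro against Vector it recovered 39.2% of 2-fold and 85.6% of 4-fold changes, and 10.8% of its calls were false. For tumors against MUC1-CD in vitro these shares were 37.5%, 89.1% and 0.24%. A list with simulated shifts was called in 10 of 10 simulations of each comparison, and 1 and 0 of 270 unshifted lists were called. The simulated noise was independent between probe sets, and far fewer probe sets changed than were called in the data. These shares check the code and need not hold for the data.

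Alternatives were pseudocounts of 1 and 64, no filter or a filter at the 60th percentile, quantile normalization, division of each array by its median, no mean-variance trend, a fit on the groups compared alone (not run on lists), the replicate number as a block, a 2-fold threshold added to the adjusted p, the mean of a gene's probe sets, camera with an estimated correlation, and leaving out each array in turn. Added after seeing the data were array weights per group, the beta-actin 3' to 5' ratio as a covariate, and only probe sets that differed by less than 0.25 (log2) between the Vector arrays. Where an alternative left out an array or rescaled the values, the filter was applied again, so the measured members of a list could differ. With 2 arrays per group, arrays were not tested as outliers within a group and group labels were not permuted. The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.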

Results

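Gene expression was measured in rat 3Y1 cells, a line of embryonic fibroblasts, on 6 Affymetrix arrays covering the rat genome. The line carried either an empty vector (Vector) or a vector for the cytoplasmic domain of the membrane mucin MUC1 (MUC1-CD), both stably transfected. The arrays fell into 3 groups of 2 biological replicates: Vector cells in culture, MUC1-CD cells in culture, and MUC1-CD cells grown as tumors under the skin of athymic mice. The stated purpose was to find genes that go with transformation and tumor growth of MUC1-CD cells. Of 31042 probe sets other than controls, 18625 passed the signal filter, and 13871 of these named a single gene, giving 10037 genes. Signals are given as mean ± SD of 2 arrays. Changes are differences of log2(signal + 16) with the standard error (SE) from limma, a scale that understates the change of genes with low signal. Adjusted p values are those of limma after Benjamini-Hochberg adjustment. The number of arrays limits their precision.

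The Vector arrays stood apart from the other arrays in their control probe sets. The ratio of the 3' to the 5' signal of Gapdh was 11.5 and 17.8 on Vector replicates 1 and 2, against 1.18 and 1.11 on the MUC1-CD culture arrays and 1.11 and 1.14 on the tumor arrays. For beta-actin the ratio was 4.15 on Vector replicate 1 and 41.7 on Vector replicate 2, and 2.97 to 3.37 on the other arrays. The 5S ribosomal RNA signal was 1635 ± 233 (SD, n = 2) in Vector cells, 242 ± 21.1 in MUC1-CD cells in culture and 282 ± 13.4 in tumors. The Cre control transcript had 3' to 5' ratios of 1.30 to 1.49 over the 6 arrays. Replicates correlated across probe sets, which are not independent replicates, at r = 0.956 in the Vector group, 0.991 in the MUC1-CD culture group and 0.987 in the tumor group. RNA quality and the Vector group cannot be told apart, because both Vector arrays and no other array had a Gapdh ratio above 1.18.

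**Figure D1:**
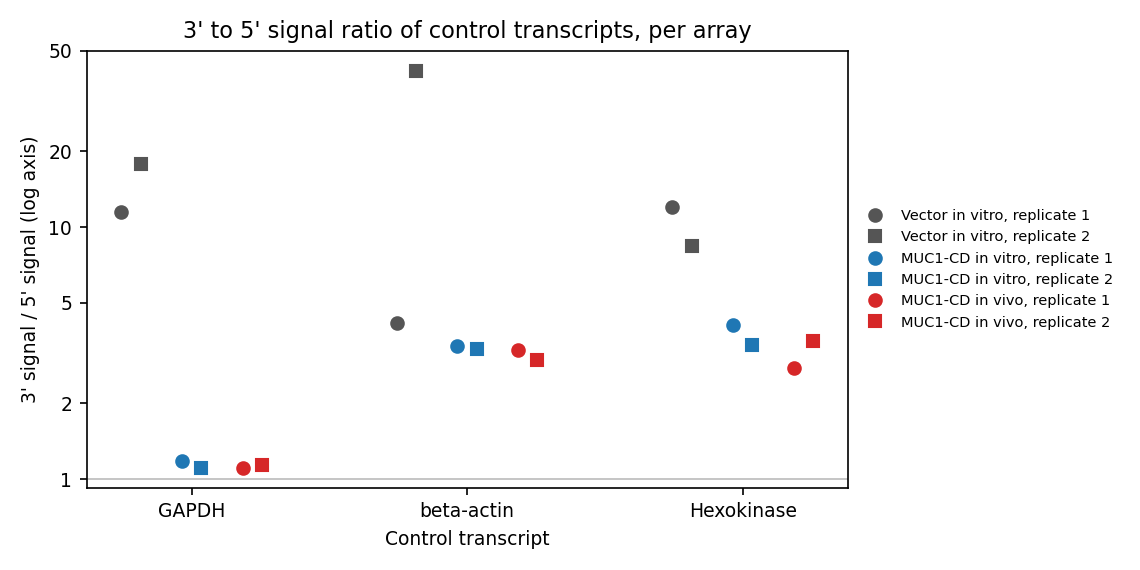
Ratio of the 3' signal to the 5' signal (log axis) of the control probe sets for Gapdh, beta-actin and hexokinase; each point is 1 array, marked by group. The Vector arrays lie at 11.5 and 17.8 for Gapdh, and the other 4 arrays lie between 1.11 and 1.18. The hexokinase signals of the Vector arrays lie below the signal filter, so their ratios are imprecise.

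The rat Muc1 probe set had a signal of 87.9 ± 6.65 (SD, n = 2) in Vector cells, with single arrays at 92.6 and 83.2. It was 35.1 ± 11.9 in MUC1-CD cells in culture (43.5 and 26.7) and 56.5 ± 6.79 in tumors (61.3 and 51.7). The probe set lay below the signal filter and was not tested. Whether it can detect the transfected sequence is not given in the sources used here, so it does not check the group labels.

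MUC1-CD cells in culture were compared with Vector cells to find which genes go with expression of the domain outside an animal. The stromelysin genes Mmp10 and Mmp3 were among the largest rises: Mmp10 rose from 102 ± 24.2 to 17056 ± 297 (SD, n = 2; log2 change 7.19 ± 0.15, limma adjusted p = 2.29e-06). Mmp3 rose by 6.48 ± 0.12 (adjusted p = 2.16e-06). As a whole, the list of matrix proteases and inhibitors was not called: 8 of 25 measured members rose and 6 fell, with the same counts adjusted over the list alone and a median of 0.13, or 0.01 without Vector replicate 2 to 0.21 without Vector replicate 1 (camera adjusted p = 0.406; adjusted p = 0.631 with an estimated correlation). Tgfbi, a secreted adhesion protein induced by TGF-beta, fell by 6.30 (SE 0.12) from 13741 ± 49.5 to 159 ± 19.2 (adjusted p = 2.16e-06). Matrix glycoproteins and proteoglycans were not called as a list: 10 of 31 measured members rose and 11 fell, with 12 rises and 11 falls adjusted over the list alone and a median of -0.11, or -0.31 without Vector replicate 2 to 0.28 without Vector replicate 1 (camera adjusted p = 0.816; adjusted p = 0.827 with an estimated correlation). Xist, the noncoding RNA that coats the inactive X chromosome, had the largest rise of the named genes, from 1.45 ± 0.354 to 7132 ± 758 (log2 change 8.67 ± 0.13, adjusted p = 1.03e-06). Its other 3 probe sets were also higher on both MUC1-CD culture arrays than on both Vector arrays. Whether the lines came from the same stock of 3Y1 cells is not given in the sources used here, so a difference between the lines and an effect of the domain cannot be told apart.

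The other largest rises on the log2 scale were those of Sncg (gamma-synuclein, 7.58), Adh1c (an alcohol dehydrogenase, 7.03), Serpinb2 (an inhibitor of plasminogen activators, 6.53), Steap4 (a metalloreductase, 6.42), Ripk4 (a kinase, 6.28), Tceal1 (6.25) and Gda (guanine deaminase, 6.22). Their adjusted p values were 2.27e-06 to 1.19e-05. The other largest falls were those of Ltbp4 (a binding protein of latent TGF-beta, -6.12), Slpi (a protease inhibitor, -5.97), Colec12 (a scavenger receptor, -5.81), the collagens Col8a2 (-5.58) and Col11a1 (-5.40), Zmym6 (-5.57), Tmeff1 (-5.47), the matrix proteoglycan Aspn (-5.42) and Car3 (a carbonic anhydrase, -5.36), with adjusted p = 6.19e-06 to 7e-05. Without Vector replicate 2, the smallest of these changes among the falls was that of Aspn (-5.04) and among the rises that of Gda (6.14).

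**Figure D2:**
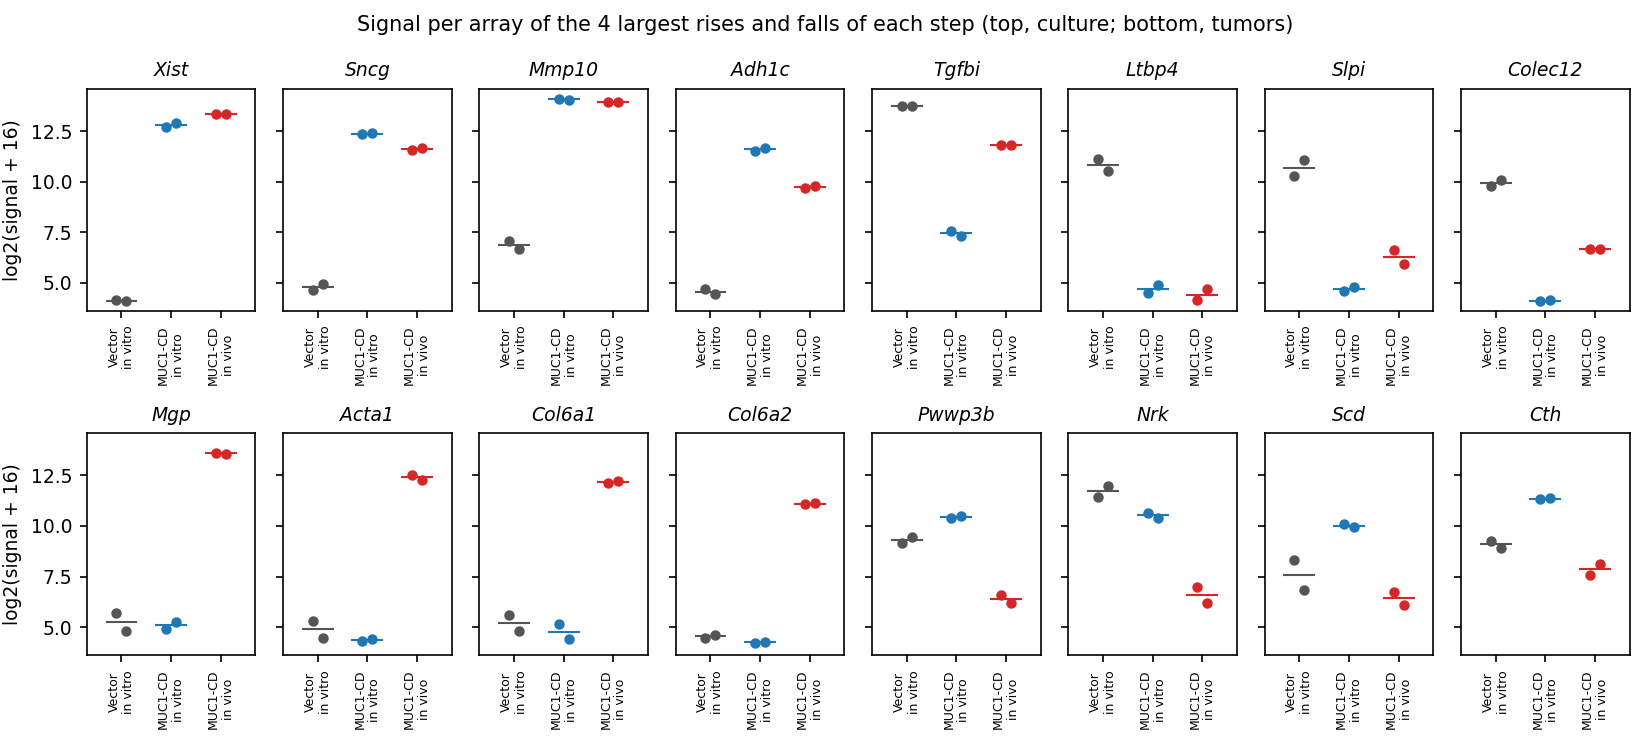
Signal per array as log2(signal + 16) of the 4 genes with the largest rise and the 4 with the largest fall from Vector to MUC1-CD cells in culture (top) and from there to tumors (bottom); each point is 1 array, colored by group, and each bar is the mean of 2 arrays. Mmp10 has means of 102 and 17056 in the culture groups, Mgp lies at 18.1 in MUC1-CD culture and 12286 in tumors, and no points of the groups compared overlap.

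In the list of cell cycle genes, 33 of 47 measured members rose and 2 fell, with 38 rises and 3 falls adjusted over the list alone and a median change of 1.05 (limma camera with a preset correlation, adjusted p = 3.16e-09; adjusted p = 0.122 with an estimated correlation). Mad2l1, of the spindle checkpoint, rose by 2.20 ± 0.14, the mitotic cyclin Ccnb2 by 1.60 ± 0.10, the kinetochore protein Cenpf by 1.87 ± 0.13 and Prc1, of the spindle midzone, by 1.45 ± 0.10 (adjusted p = 9.73e-05 to 0.000139). Over this list, Vector replicate 1 minus replicate 2 had a median of -0.10, and the median change without Vector replicate 2 was 1.13. In the list of cholesterol synthesis, 17 of 20 measured members rose and 1 fell, with the same counts adjusted over the list alone and a median of 1.37 (camera adjusted p = 8.23e-08; adjusted p = 0.122 with an estimated correlation). Cyp51, lanosterol demethylase, rose by 2.50 ± 0.11, Acat2 by 2.44 ± 0.12, the isomerase Idi1 by 2.09 ± 0.12 and the sterol dehydrogenase Nsdhl by 2.19 ± 0.15 (adjusted p = 2.74e-05 to 0.000125). In the list of fatty acid and lipid synthesis, 18 of 25 measured members rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.69 (camera adjusted p = 1.63e-05; adjusted p = 0.122 with an estimated correlation). The desaturase Fads1 rose by 1.37 ± 0.10, the lipid droplet protein Plin2 by 1.05 ± 0.09, the elongase Elovl6 by 1.47 ± 0.14 and the fatty acid carrier Fabp4 by 1.96 ± 0.19 (adjusted p = 0.000175 to 0.000426). The median differences between the Vector arrays over the cholesterol and fatty acid lists were 0.13 and 0.06, and the median changes without Vector replicate 2 were 1.49 and 0.83.

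Among MAPK and EGFR feedback and immediate early genes, 15 of 27 measured members rose and 6 fell, with the same counts adjusted over the list alone and a median of 0.52 (camera adjusted p = 0.0118; adjusted p = 0.182 with an estimated correlation). Areg, a ligand of EGFR, rose from 145 ± 45.5 to 4881 ± 311 (SD, n = 2; log2 change 4.95 ± 0.20, limma adjusted p = 2.49e-05). The phosphatases of MAP kinases Dusp6 and Dusp5 rose by 2.62 ± 0.11 and 2.30 ± 0.15, and the transcription factor gene Etv4 by 1.95 ± 0.13 (adjusted p = 2.56e-05 to 0.000107). Over this list the Vector arrays differed by a median of 0.10, and the median change without Vector replicate 2 was 0.68.

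In the list of MYC and ribosome biogenesis genes, 21 of 31 measured members fell and 1 rose, with 21 falls and 2 rises adjusted over the list alone and a median of -0.61 (camera adjusted p = 0.000114; adjusted p = 0.123 with an estimated correlation). The transcription factor gene Myc fell by 3.81 (SE 0.16) from 3418 ± 575 to 227 ± 0.778 (SD, n = 2; limma adjusted p = 2.61e-05). Of the nucleolar genes, Gnl3 fell by 1.92 (SE 0.09), Mybbp1a fell by 1.49 (SE 0.12) and Bop1 fell by 2.13 (SE 0.21) (adjusted p = 3.96e-05 to 0.000447). Myc and Bop1 are the 2 members on chromosome 7 of the GRCr8 assembly, whose 656 measured genes had a median change of -0.65. The 40 neighbouring genes from Myc to Eppk1 had a median of -1.18, and 90% of them were lower. Gnl3 lies on chromosome 16, with a median of -0.35 over 292 genes. In gene order, the medians of its eighths 1 to 4 lay between -0.72 and -1.13, and those of eighths 5 to 8 between -0.14 and 0.08. The members outside chromosome 7 had a median of -0.60, and 19 of them fell. Members on other chromosomes with mostly lower stretches, such as chromosome 16, were not left out. Over the list the Vector arrays differed by a median of 0.17, and the median change without Vector replicate 2 was -0.71.

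Of 28 lists with at least 5 measured members, camera called 6 in this comparison with the preset correlation and 0 with an estimated one (5 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 25. Over all probe sets, limma called 8522 of 18625 changed (45.8%), 4665 higher and 3857 lower, and by gene 2124 rose and 2501 fell. Division of each array by its median moved the median change of all probe sets from 0.07 to -0.25 and the share of calls that were higher from 54.7% to 33.2%. The count was 4760 and 4391 without MUC1-CD culture replicate 1 or 2, where the lone array is assumed to vary like the other groups.

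Tumors were compared with MUC1-CD cells in culture to find which genes go with growth in the animal. Genes of the extracellular matrix had several of the largest rises: Mgp, matrix Gla protein, rose from 18.1 ± 5.87 to 12286 ± 407 (SD, n = 2; log2 change 8.50 ± 0.31, limma adjusted p = 7.46e-05), and Postn, periostin, rose by 6.19 ± 0.15 (adjusted p = 4.41e-05). The largest fall was that of Pwwp3b, which fell by 4.05 (SE 0.20) from 1366 ± 87.8 to 67.8 ± 16.1 (adjusted p = 0.000147). Markers of macrophages, endothelium and skeletal muscle, cell types of the host, had median changes of 2.51, 1.48 and 2.22 on the same arrays. Per the labels, tumor RNA went through freezing, homogenization and column steps that cultured cells did not, so growth setting and RNA preparation cannot be told apart.

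The other largest rises were those of Acta1 (skeletal muscle actin, 8.05), the collagen VI chains Col6a1 (7.40) and Col6a2 (6.86), Hbb (a hemoglobin chain, 6.83), Bcl2a1 (an inhibitor of apoptosis, 6.49), Apoe (an apolipoprotein, 6.12), Cd74 (the invariant chain of MHC class II, 6.01) and Mmp2 (a gelatinase, 5.76), at adjusted p = 6.41e-05 to 0.000240. The other largest falls were those of Nrk (a kinase, -3.95), Scd (stearoyl-CoA desaturase, -3.60), Cth (cystathionine gamma-lyase, -3.50), Abhd3 (-3.39), Ddah1 (-3.26), Elmod1 (-3.19), Ankrd1 (-3.18), Cfap299 (-3.17) and Zcchc18 (-3.07), with adjusted p = 0.000125 to 0.00411.

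In the list of cholesterol synthesis, 18 of 20 measured members fell and 0 rose, with 19 falls and 0 rises adjusted over the list alone and a median of -1.56 (camera adjusted p = 2.47e-16; adjusted p = 0.122 with an estimated correlation). Acat2 fell by 2.67 (SE 0.12), Dhcr7 fell by 2.56 (SE 0.14), Pmvk fell by 1.92 (SE 0.11) and Idi1 fell by 1.88 (SE 0.12) (adjusted p = 0.000125 to 0.000323). Among genes of fatty acid and lipid synthesis, 16 of 25 measured members fell and 0 rose, with 17 falls and 1 rise adjusted over the list alone and a median of -1.09 (camera adjusted p = 7.23e-09; adjusted p = 0.122 with an estimated correlation). The acyl-CoA synthetase gene Acsl3 fell by 1.85 (SE 0.12) and Acsl1 fell by 2.19 (SE 0.16), the synthase Fasn fell by 1.50 (SE 0.10) and Fads1 fell by 1.42 (SE 0.10) (adjusted p = 0.000306 to 0.000463). Among cell cycle genes, 23 of 47 measured members fell and 0 rose, with 24 falls and 1 rise adjusted over the list alone and a median of -0.54 (camera adjusted p = 7.09e-08; adjusted p = 0.122 with an estimated correlation). Cenpf fell by 1.58 (SE 0.13), the checkpoint kinase gene Bub1b fell by 1.21 (SE 0.14), the kinesin gene Kif20a fell by 1.57 (SE 0.20) and the cyclin gene Ccnb1 fell by 0.80 (SE 0.11) (adjusted p = 0.000686 to 0.00504).

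Among collagen genes, 11 of 19 measured members rose and 2 fell, with 13 rises and 2 falls adjusted over the list alone and a median of 0.80 (camera adjusted p = 8.54e-06; adjusted p = 0.122 with an estimated correlation). Col6a3 rose by 5.47 ± 0.19 and Col3a1, a fibrillar collagen, by 1.51 ± 0.08. Among matrix glycoproteins and proteoglycans, 17 of 31 measured members rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.97 (camera adjusted p = 9.7e-07; adjusted p = 0.122 with an estimated correlation). Nid2, of basement membranes, and the proteoglycan Ogn rose by 2.86 ± 0.13 and 2.87 ± 0.13. Among matrix proteases and inhibitors, 9 of 25 measured members rose and 1 fell, with 13 rises and 2 falls adjusted over the list alone and a median of 0.33 (camera adjusted p = 0.000355; adjusted p = 0.209 with an estimated correlation). Mmp12, the macrophage elastase, rose by 3.24 ± 0.24, the fibroblast activation protein gene Fap by 3.23 ± 0.28 and the cathepsin gene Ctss by 3.19 ± 0.34. Over the alternatives run on lists, other than the estimated correlation, the median of the protease list ranged from 0.05 to 0.41. Among pericyte and stromal markers on the same arrays, 5 of 14 measured members rose and 1 fell, with 7 rises and 2 falls adjusted over the list alone and a median of 0.56 (camera adjusted p = 0.0157; adjusted p = 0.238 with an estimated correlation). Dcn, Lum and Cd248 rose by 3.78 ± 0.23, 4.45 ± 0.34 and 4.46 ± 0.39, and Pdgfra fell by 0.59 (SE 0.08). With the 60th percentile filter the median of the pericyte and stromal list was 0.06. The adjusted p values of the members of these lists named here were 6.75e-05 to 0.00570.

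Among macrophage markers, 12 of 17 measured members rose and 1 fell, with 13 rises and 1 fall adjusted over the list alone and a median of 2.51 (camera adjusted p = 8.48e-07; adjusted p = 0.122 with an estimated correlation). Aif1 had a signal of 0.600 ± 0.283 in culture and 622 ± 25.0 in tumors (SD, n = 2; log2 change 5.26 ± 0.33, limma adjusted p = 0.000280), and Coro1a, the complement gene C1qa and the integrin gene Itgb2 rose by 5.45 ± 0.34, 4.06 ± 0.26 and 4.33 ± 0.28. Without tumor replicate 1 the median of the list was 1.12, with the filter applied again, so its measured members may differ. Among endothelial markers, 8 of 11 measured members rose and 0 fell, with the same counts adjusted over the list alone and a median of 1.48 (camera adjusted p = 0.000345; adjusted p = 0.123 with an estimated correlation). The water channel gene Aqp1 rose by 5.29 ± 0.24 and the VEGF receptor gene Flt1 by 2.50 ± 0.24. Among skeletal muscle markers, 11 of 17 measured members rose and 2 fell, with 12 rises and 2 falls adjusted over the list alone and a median of 2.22 (camera adjusted p = 1.63e-05; adjusted p = 0.122 with an estimated correlation). The calcium pump gene Atp2a1, Actn3 and the troponin gene Tnnc2 rose by 4.20 ± 0.24, 2.80 ± 0.26 and 4.61 ± 0.50. Of the erythroid and the lymphoid or granulocyte markers 2 each passed the filter, too few for a list test: Hbb, S100a9 and Lck rose by 6.83 ± 0.36, 3.58 ± 0.36 and 0.88 ± 0.21 (adjusted p = 0.000179 to 0.0348), and Slc4a1 did not pass (0.49 ± 0.38, adjusted p = 0.425).

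Lists of immune and signalling genes were tested on the same arrays as these host markers. Among genes of MHC and antigen presentation, 11 of 21 measured members rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.77 (camera adjusted p = 3.6e-06; adjusted p = 0.139 with an estimated correlation). The class II genes RT1-Db1 and RT1-Da rose by 3.89 ± 0.22 and 2.49 ± 0.18. Among NF-kB targets, 10 of 23 measured members rose and 1 fell, with 12 rises and 2 falls adjusted over the list alone and a median of 0.48 (camera adjusted p = 0.000567; adjusted p = 0.137 with an estimated correlation). The adhesion gene Vcam1 rose by 4.67 ± 0.25, and the cyclooxygenase gene Ptgs2 fell by 1.55 (SE 0.15). Without MUC1-CD culture replicate 1 the median of the NF-kB list was 0.75. Among MAPK and EGFR feedback and immediate early genes, 6 of 27 measured members rose and 0 fell, with 8 rises and 2 falls adjusted over the list alone and a median of 0.33 (camera adjusted p = 0.0102; adjusted p = 0.181 with an estimated correlation). The immediate early genes Egr1, Fos and Egr2 rose by 2.07 ± 0.12, 3.83 ± 0.22 and 2.59 ± 0.20. Over the alternatives run on lists, other than the estimated correlation, the median of the MAPK list ranged from 0.07 to 0.39.

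Among complement components, 7 of 10 measured members rose and 2 fell, with the same counts adjusted over the list alone and a median of 1.09 (camera adjusted p = 0.0118; adjusted p = 0.190 with an estimated correlation). The C1q chain gene C1qb and C3 rose by 3.29 ± 0.37 and 2.61 ± 0.33. Among TGF-beta and SMAD targets, 5 of 19 measured members rose and 2 fell, with 6 rises and 2 falls adjusted over the list alone and a median of 0.30 (camera adjusted p = 0.0334; adjusted p = 0.209 with an estimated correlation). Tgfbi rose by 4.36 ± 0.12, opposite to its fall in culture. Among WNT and beta-catenin targets, 6 of 17 measured members rose and 1 fell, with the same counts adjusted over the list alone and a median of 0.57 (camera adjusted p = 0.0323; adjusted p = 0.209 with an estimated correlation). The feedback gene Axin2 rose by 3.35 ± 0.31. The complement call was lost without tumor replicate 1 or 2, with medians of 0.57 and 0.70. Both lie below the 1.09 of all arrays. The filter was applied again without each array, so the members measured may differ, and the loss need not rest on 1 array. The TGF-beta call was lost without tumor replicate 2, and the WNT call without tumor replicate 2 or MUC1-CD culture replicate 1. Without tumor replicate 1 the TGF-beta and WNT medians were 0.53 and 0.31. Over the alternatives run on lists, other than the estimated correlation, the TGF-beta median ranged from 0.03 to 0.53 and the WNT median from 0.11 to 0.63. Over the alternatives run on lists, other than the estimated correlation, the adjusted p ranged from 0.00224 to 0.214 for complement, 0.00505 to 0.337 for TGF-beta, 0.00734 to 0.669 for WNT, 0.00397 to 0.126 for MAPK, 4.4e-06 to 0.0851 for endothelium, 1.05e-07 to 0.405 for muscle and 0.000944 to 0.663 for pericytes.

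**Figure D3:**
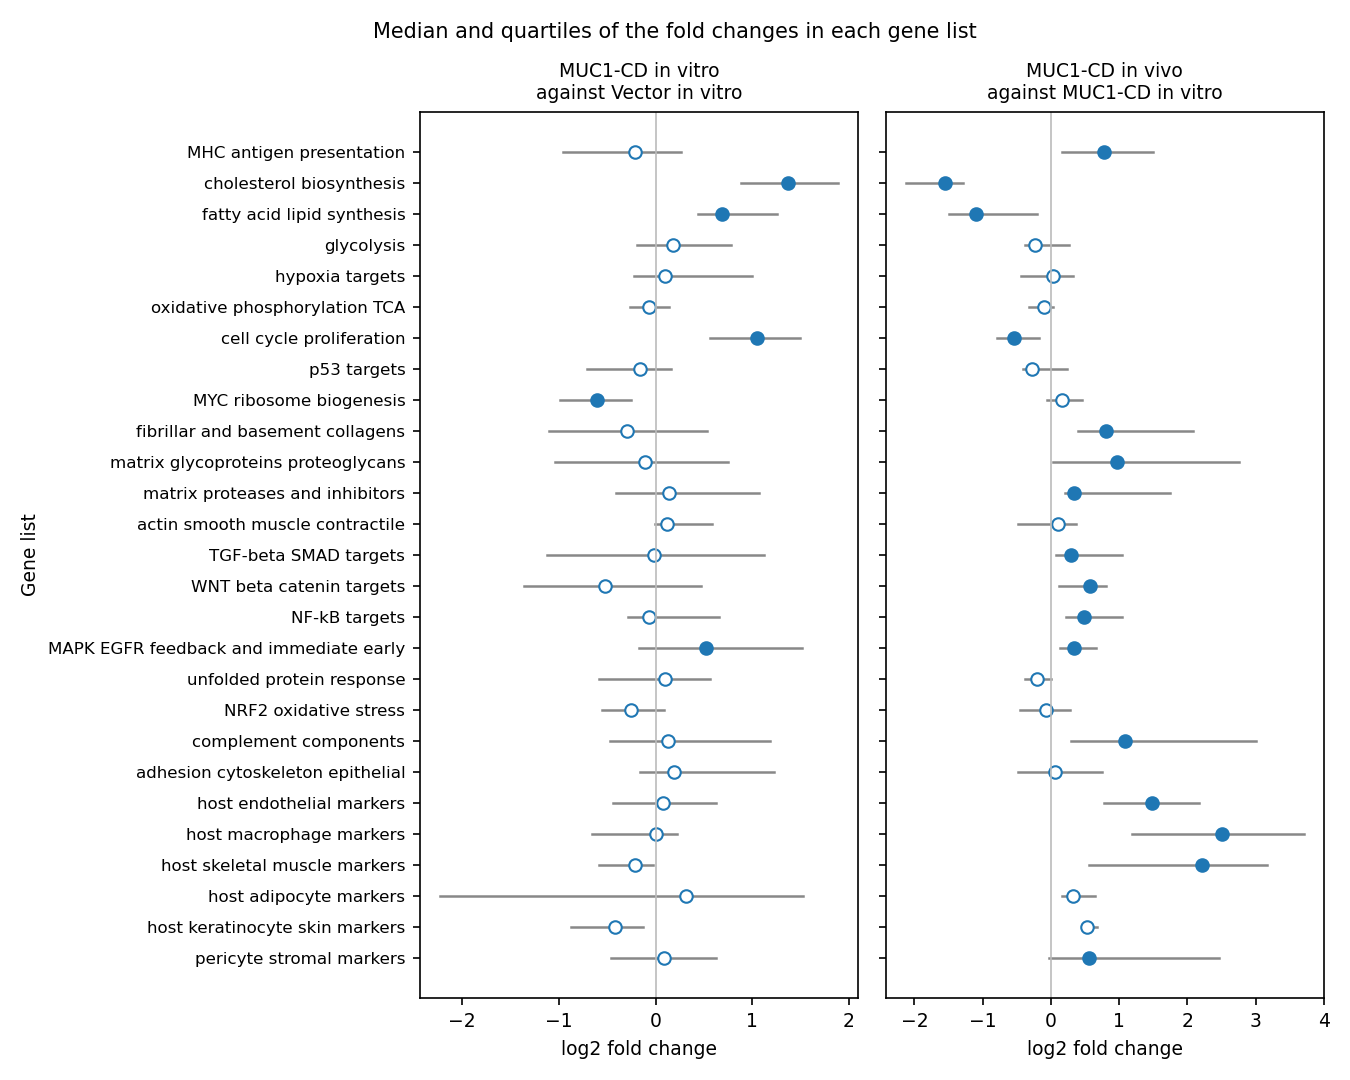
Median (circle) and quartiles (line) of the log2 fold changes of the members of gene lists fixed before the data were examined, for MUC1-CD in vitro against Vector (left) and tumors against MUC1-CD in vitro (right); filled circles mark lists called by camera with the preset correlation, adjusted p under 0.05. The cholesterol list has medians of 1.37 and -1.56, the cell cycle list 1.05 and -0.54, and the macrophage markers 0.00 and 2.51.

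Camera called 17 lists in this comparison with the preset correlation, 14 of them upward, and 0 with an estimated correlation (12 at an unadjusted p under 0.05), and fry called 23. Over all probe sets, limma called 2952 of 18625 changed (15.8%), 1590 higher and 1362 lower, and by gene 986 rose and 900 fell. Division of each array by its median moved the median change of all probe sets from 0.05 to -0.21 and the share of calls that were higher from 53.9% to 22.3%. Single arrays moved the count: it was 679 and 683 without MUC1-CD culture replicate 1 or 2, and 572 and 646 without tumor replicate 1 or 2. It was 8097 and 8059 without Vector replicate 1 or 2, whose spread enters the shared estimate. A fit on these groups alone called 8049.

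Tumors against Vector cells gave the end points of the series, in which construct, growth setting and RNA preparation all differ, with Gapdh 3' to 5' ratios of 1.11 and 1.14 in tumors against 11.5 and 17.8 in Vector cells. Xist again had the largest rise (log2 change 9.22 ± 0.13, limma adjusted p = 6.86e-07), followed by Mgp (8.33), the protocadherin gene Pcdh9 (7.78), Steap4 (7.57) and Acta1 (7.51). Ltbp4 fell by 6.41 (SE 0.33), the largest fall (adjusted p = 3.37e-05), followed by Tmcc3 (-5.59), the semaphorin gene Sema3e (-5.40), Papss2, of sulfate activation (-5.38), and the glutathione transferase gene Gsta4 (-5.37). Among MAPK and EGFR feedback and immediate early genes, 17 of 27 measured members rose and 2 fell, with the same counts adjusted over the list alone and a median of 1.15 (camera adjusted p = 4.79e-05; adjusted p = 0.122 with an estimated correlation). Areg and Dusp6 rose by 4.32 ± 0.20 and 2.64 ± 0.11. Among matrix proteases and inhibitors, 16 of 25 measured members rose and 4 fell, with 17 rises and 4 falls adjusted over the list alone and a median of 1.64 (camera adjusted p = 0.00104; adjusted p = 0.221 with an estimated correlation). Mmp3 and Mmp10 rose by 6.89 ± 0.12 and 7.07 ± 0.15. Among cell cycle genes, 21 of 47 measured members rose and 5 fell, with the same counts adjusted over the list alone and a median of 0.47, which turned to -0.09 when each array was divided by its median (camera adjusted p = 0.00247; adjusted p = 0.123 with an estimated correlation). Among MYC and ribosome biogenesis genes, 17 of 31 measured members fell and 3 rose, with the same counts adjusted over the list alone and a median of -0.46 (camera adjusted p = 0.00277; adjusted p = 0.181 with an estimated correlation). Myc fell by 3.01 (SE 0.16).

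Of the NF-kB targets, 13 of 23 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.84 (camera adjusted p = 0.000274; adjusted p = 0.123 with an estimated correlation). Bcl2a1 and Vcam1 rose by 6.35 ± 0.38 and 4.19 ± 0.25. Of the MHC and antigen presentation genes, 13 of 21 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.86 (camera adjusted p = 0.00104; adjusted p = 0.209 with an estimated correlation). Cd74 and Psmb8 rose by 4.83 ± 0.25 and 1.99 ± 0.16. The median of that list was 0.52 without Vector replicate 2. Of the macrophage markers, 13 of 17 rose and 1 fell, with 14 rises and 1 fall adjusted over the list alone and a median of 2.59 (camera adjusted p = 8.35e-05; adjusted p = 0.122 with an estimated correlation). Cd14 and Coro1a rose by 2.60 ± 0.14 and 5.67 ± 0.34.

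Of the skeletal muscle markers, 11 of 17 rose and 3 fell, with 12 rises and 3 falls adjusted over the list alone and a median of 2.19 (camera adjusted p = 0.0146; adjusted p = 0.190 with an estimated correlation). Atp2a1 and Tnni2 rose by 3.46 ± 0.24 and 3.08 ± 0.28. Of the pericyte and stromal markers, 10 of 14 rose and 3 fell, with the same counts adjusted over the list alone and a median of 1.31 (camera adjusted p = 0.0161; adjusted p = 0.238 with an estimated correlation). Cspg4 and Dcn rose by 5.02 ± 0.17 and 4.43 ± 0.23. Of the complement components, 7 of 10 rose and 2 fell, with the same counts adjusted over the list alone and a median of 2.16 (camera adjusted p = 0.0334; adjusted p = 0.212 with an estimated correlation). C1r and C1s rose by 1.98 ± 0.10 and 2.35 ± 0.14. Without Vector replicate 1 the muscle and complement calls were lost, with medians of 1.99 and 1.88. The complement call was also lost without tumor replicate 1 or 2, with medians of 0.88 and 1.29. The filter was applied again in these runs, so the members measured may differ. Over the alternatives run on lists, other than the estimated correlation, the adjusted p ranged from 0.000181 to 0.859 for muscle, 0.00193 to 0.254 for complement, 0.000321 to 0.160 for MHC and antigen presentation, 2.97e-05 to 0.104 for proteases and 0.000458 to 0.104 for pericytes. The median of the muscle list turned to -0.50 over probe sets that differed by less than 0.25 (log2) between the Vector arrays, an alternative chosen after seeing the data.

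Camera called 11 lists in this comparison with the preset correlation, 10 of them upward, and 0 with an estimated correlation (6 at an unadjusted p under 0.05), and fry called 26. Over all probe sets, limma called 9589 of 18625 different (51.5%), 5422 higher and 4167 lower in tumors than in Vector cells. Division of each array by its median moved the median change from 0.12 to -0.46 and the share of calls that were higher from 56.5% to 25.1%. The count was 5884 and 6031 without tumor replicate 1 or 2. Alternatives called lists that the preset test did not: matrix glycoproteins (preset adjusted p = 0.0549) upward in 9 (lowest 0.00133), 2 of them added after seeing the data. Oxidative phosphorylation (0.0805) was called downward in 5 (lowest 0.0181), collagens (0.0805) upward in 3 (lowest 0.00513) and NRF2 targets (0.127) downward in 3 (lowest 0.0295), 1 of each so added. Endothelial markers (0.199) were called upward in 1 (lowest 0.00767), and the unfolded protein response (0.406) downward in 1 (lowest 0.0346), so added.

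Some genes changed the same way from Vector to MUC1-CD cells in culture and again from there to tumors. Vcan, the matrix proteoglycan versican, rose by 3.83 ± 0.33 in the first step and 3.24 ± 0.33 in the second (limma adjusted p = 0.000272 and 0.00161). The angiotensin receptor gene Agtr2 rose by 4.62 and 2.87, the secreted phospholipase gene Pla2g2a by 2.75 and 3.55, Qpct by 2.71 and 2.90 and Plaat3 by 2.66 and 2.69. Tmcc3, which lies on chromosome 7, fell by 2.94 and then fell by 2.65 (adjusted p = 0.000229 and 0.00103). Gsta4 had changes of -2.87 and -2.50, Phgdh, of serine synthesis, -2.31 and -2.59, the WNT receptor gene Fzd4 -1.99 and -2.97 and Peg12 -2.59 and -1.96.

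By probe set, 665 changed in the same direction in both steps, 369 upward and 296 downward. Another 1090 changed in opposite directions, 548 higher and then lower and 542 lower and then higher. Independent lists of these sizes would share 680.3 in the same and 670.4 in opposite directions. The correlation of the fold changes of both steps, across probe sets, was -0.12 against a mean of -0.26 in 100 simulations of unchanged groups that shared the MUC1-CD culture arrays. The covariance was -0.0917 against a simulated -0.0121, a difference of -0.0795. With 2 shared arrays no split that keeps 2 arrays on each side was possible, so part of the opposite changes may come from the shared arrays. The count in the same direction was 101 and 104 without MUC1-CD culture replicate 1 or 2 (independent lists 89.2 and 82.1), and 119 and 133 without tumor replicate 1 or 2 (108 and 121). It was 2423 and 2101 without Vector replicate 1 or 2 (independent lists 2524 and 2399), 1294 with each array divided by its median (1229.6) and 503 without a filter (353).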

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

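The tests of probe sets higher and of probe sets lower in MUC1-CD cells were chosen only after the result was seen. Control probe sets lie outside the measurement that the comparisons used, and they stood out because those of Gapdh and hexokinase had higher signal in MUC1-CD cells in culture than in Vector cells, the control group. The log2 ratio of mean signals for Gapdh was 1.10 at the 3' end, 3.15 in the middle and 4.54 at the 5' end. For hexokinase it was 2.96 at the 3' end, 3.58 in the middle and 4.43 at the 5' end, but its Vector signals (4.30 to 51.6) lay below the signal filter, and with those raised to the filter signal the ratios were 2.51, 0.84 and 0.63. The beta-actin signals of both groups overlapped: the 3' signal was 23050 and 7857 on the Vector arrays and 10713 and 11388 on the MUC1-CD culture arrays.

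Of the kept probe sets, 4665 were higher and 3857 lower in MUC1-CD cells in culture than in Vector cells. RNA loss in the Vector arrays may contribute to both, the falls through the common scaling of the arrays, and it stays open for both. The median of Vector replicate 1 minus replicate 2, less that over probe sets not called, was 0.0746 (log2) over the rises and -0.0398 over the falls, as more and less loss on the array with the higher Gapdh and beta-actin ratios would give. The rises and falls were called with these same Vector arrays, so a larger deviation of replicate 2 for any reason could give the same signs. A biological effect of MUC1-CD also stays open, since RNA quality and the construct differ between the same arrays.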

How the results depend on the processing

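Array weights, the beta-actin covariate, the probe sets alike on both Vector arrays and the tests on them were chosen only after the result was seen. Without 1 array at a time, limma called 4391 to 11503 probe sets in MUC1-CD in vitro against Vector, 572 to 8097 in tumors against MUC1-CD in vitro, 5884 to 12434 in tumors against Vector, and 101 to 2423 changed the same way in both steps. A 2-fold threshold, which removes small changes, left 4618, 1445, 5551 and 247. For tumors against MUC1-CD in vitro the count was 8049 in a fit without the Vector arrays, 7801 with array weights (which kept all 2952 calls) and 7934 with the covariate. Vector replicates differed by an SD of 0.616 (log2) across probe sets, against 0.257 in MUC1-CD culture and 0.284 in tumors. A fit without the Vector arrays leaves this spread out, and the weights (0.286 for Vector, 2.08 and 1.69 otherwise) reduce it. The covariate separates the Vector arrays (beta-actin ratios 4.15 and 41.7) and can absorb it. The lower main count thus goes with the Vector spread in the shared estimate. The count changed the same way in both steps was 1294 with division by the median, 1384 with array weights and 1959 with the covariate. Independent lists would share 1229.6, 1504 and 2260. Calls in tumors against MUC1-CD in vitro rose under these settings too (4166, 7801 and 7934, against 2952). No other cause was tested. The lists called fell to 0 with an estimated correlation. In MUC1-CD in vitro against Vector the estimates for the cell cycle and fatty acid lists were -0.00076 and -0.0115. These lie below the preset 0.01, so a higher correlation did not end those calls. With an estimated correlation, camera rests on the 3 residual degrees of freedom of the fit, which weakens every list test. These 2 lists had preset adjusted p of 3.16e-09 and 1.63e-05, and both came to 0.122. Calls lost in this way therefore do not tell which lists shifted. The muscle list in tumors against Vector reversed to -0.50 over probe sets alike on both Vector arrays (camera adjusted p = 0.859). In tumors against MUC1-CD in vitro its median was 0.57 there, the lowest over the alternatives. This restriction left 7509 of 18625 probe sets and does not change the fold change of a probe set. The medians therefore moved because other members were left. Whether anything besides the few degrees of freedom ended the calls, and why the muscle members that were left differ, were not tested. The 60th percentile filter left 75 of 84 list results measured, ended 8 calls and gained 0; over all 84, quantile normalization ended 2 and gained 3, and division by the median ended 0 and gained 6. No named-gene result reversed where it was measured (326 of 377 under that filter, 210 over probe sets alike on both Vector arrays, at least 371 without 1 array), and the most calls lost were 45, without MUC1-CD in vitro replicate 1 or tumor replicate 2. The replicate numbers did not pair the arrays (correlations of replicate differences across probe sets -0.02, -0.03 and -0.04); with the replicate block the counts were 8130, 2390, 9208 and 508, and no list call moved. The 18625 kept probe sets leave out those at low signal, where background limits what the arrays can show.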

Other observations

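The tests of the chromosome 7 share, of the windows of neighbouring genes, of the host markers and of dilution were chosen only after the result was seen. The list tests were not. The test of Vector RNA bias over the windows was written before its own result was seen, but its windows were chosen after the data were seen. Lists that camera did not call held genes that changed strongly in both directions. Of all 10037 genes, 2124 rose and 2501 fell in MUC1-CD in vitro against Vector, and 986 rose and 900 fell in tumors against MUC1-CD in vitro. Called members alone therefore do not set a list apart from other genes. Among p53 targets in MUC1-CD cells against Vector cells, 1 of 17 rose and 7 fell (the same adjusted over the list alone, median -0.16, or -0.43 without MUC1-CD culture replicate 2 to -0.01 without Vector replicate 1, camera adjusted p = 0.343). Mdm2, a gene of chromosome 7 for the ligase that limits p53, fell by 1.43 (SE 0.11), the kinase gene Plk2 fell by 1.86 (SE 0.18) and the death receptor gene Fas rose by 2.68 ± 0.18 (limma adjusted p = 0.000117 to 0.000388). In the unfolded protein response list, 6 of 27 rose and 7 fell (7 and 7 adjusted over the list alone, median 0.10, or -0.09 without Vector replicate 2 to 0.15 without MUC1-CD culture replicate 2, camera adjusted p = 0.978), with a mean of -0.14 opposite in sign to the median. The transcription factor genes Atf4 and Ddit3 fell by 1.80 and fell by 1.72; both lie on chromosome 7. Psat1, of serine synthesis, fell by 1.39 in culture and then fell by 1.51 in tumors. Among NRF2 targets, 2 of 23 rose and 7 fell (the same adjusted over the list alone, median -0.26, or -0.26 without tumor replicate 1 to -0.21 without Vector replicate 1, camera adjusted p = 0.265). The metallothionein gene Mt2A fell by 3.15 (SE 0.14) and the glutathione transferase gene Gsta1 fell by 4.78 (SE 0.30). Among hypoxia targets, 8 of 21 rose and 5 fell (9 and 5 adjusted over the list alone, median 0.10, or 0.10 without tumor replicate 1 to 0.29 without Vector replicate 1, camera adjusted p = 0.259). Stc1, a secreted glycoprotein, rose by 2.66 ± 0.16, and Ndrg1, on chromosome 7, fell by 1.76 (SE 0.10). Among adhesion and epithelial genes, 8 of 23 rose and 4 fell (the same adjusted over the list alone, median 0.19, or 0.14 without MUC1-CD culture replicate 1 to 0.21 without MUC1-CD culture replicate 2, camera adjusted p = 0.259). In tumors against MUC1-CD culture, 7 of 23 rose and 5 fell (8 and 5 adjusted over the list alone, median 0.05, or 0.05 without Vector replicate 1 to 0.16 without MUC1-CD culture replicate 1, camera adjusted p = 0.540). Jup, plakoglobin, fell by 3.32 (SE 0.25) and then rose by 3.46 ± 0.25, the keratin gene Krt8, on chromosome 7, fell by 3.02 (SE 0.23) in culture, and Cdh1, E-cadherin, rose by 4.70 ± 0.29 in tumors.

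Of the glycolysis genes in MUC1-CD cells in culture, 4 of 17 rose and 3 fell (the same adjusted over the list alone, median 0.18, or 0.05 without Vector replicate 2 to 0.23 without MUC1-CD culture replicate 1, camera adjusted p = 0.576). Of the oxidative phosphorylation genes, 4 of 30 rose and 5 fell (3 and 5 adjusted over the list alone, median -0.07, or -0.09 without MUC1-CD culture replicate 2 to -0.04 without MUC1-CD culture replicate 1, camera adjusted p = 0.638). Of the actin and smooth muscle genes, 5 of 18 rose and 2 fell (the same adjusted over the list alone, median 0.11, or 0.08 without MUC1-CD culture replicate 2 to 0.35 without Vector replicate 1, camera adjusted p = 0.477). Of the adipocyte markers, 3 of 6 rose and 2 fell (the same adjusted over the list alone, median 0.31, or 0.01 without tumor replicate 1 to 0.42 without Vector replicate 1, camera adjusted p = 0.944), with a mean of -0.65. Of the keratinocyte markers, 1 of 5 rose and 1 fell (the same adjusted over the list alone, median -0.42, or -0.45 without Vector replicate 1 to -0.31 without MUC1-CD culture replicate 2, camera adjusted p = 0.655). In tumors against MUC1-CD cells in culture, camera called none of the following lists. Camera adjusted p was 0.615 for glycolysis, 0.523 for hypoxia, 0.0824 for oxidative phosphorylation, 0.492 for p53. It was 0.803 for actin, 0.0549 for the unfolded protein response, 0.316 for NRF2, 0.375 for adipocytes, 0.507 for keratinocytes and 0.140 for MYC targets. Alternatives called some of them: the unfolded protein response downward in 8, 2 of them added after seeing the data (lowest adjusted p = 0.0141), oxidative phosphorylation downward in 5, 1 of them so added (0.0117), and adipocytes (0.0449) and MYC targets (0.0496) upward in 1 each. Some lists called in tumors had members that changed both ways in culture. Of the collagens, 6 of 19 rose and 8 fell (the same adjusted over the list alone, median -0.30, or -0.40 without Vector replicate 2 to -0.01 without Vector replicate 1, camera adjusted p = 0.523), with a mean of 0.01, and 1 alternative, added after seeing the data, called the list downward (adjusted p = 0.0133). The collagen gene Col8a1 rose by 4.49 ± 0.15. Of the WNT targets, 4 of 17 rose and 8 fell (the same adjusted over the list alone, median -0.52, or -0.73 without Vector replicate 1 to -0.46 without MUC1-CD culture replicate 1, camera adjusted p = 0.484). The WNT antagonist gene Sfrp4 rose by 5.12 ± 0.17.

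Genes in stretches of chromosomes 7 and 16 were lower in MUC1-CD cells than in Vector cells. A few strongly changed genes would not give the 74.7% of 656 chromosome 7 genes that were lower, against at most 59.0% in 10000 random sets. Chromosome 7 had the highest share of all chromosomes. Chromosomes 16 (67.1%), 6 (64.5%), 12 (62.8%) and 10 (61.6%) also lay above 59.0%, a maximum drawn for sets of the size of chromosome 7. RNA bias that differs between the Vector arrays is argued against too. The median of Vector replicate 1 minus replicate 2 over the genes of the windows there was 0.0468 (log2), above 95% of random sets (-0.0853 to 0.000600), while the explanation needs a value below them. Bias shared by both Vector arrays, whose Gapdh ratios were 11.5 and 17.8, cannot show in this difference and stays open. Of 239 windows of 40 neighbouring genes, 21 had at least 80% of genes lower and 2 at least 80% higher, against at most 2 and 1 in 1000 shuffles of gene order; from culture to tumors these were 2 and 7, against at most 1 and 2. The windows mostly lower were 9 of 16 on chromosome 7 and 3 of 7 on chromosome 16, whose genes had medians of -0.91 in culture and 0.09 from culture to tumors, and 3 of 11 on chromosome 6, 3 of 21 on 10, 2 of 16 on 2 and 1 of 8 on 12. Genes outside these windows had medians in culture of -0.27 on chromosome 7 and -0.07 on chromosome 16. The window from Myc to Eppk1, mostly lower in culture, was among those mostly higher from culture to tumors, with a median of 0.37. Neighbouring genes thus also shifted together from culture to tumors, so such windows alone do not show a difference in copies. A hypothesis is that the lines may differ in copies of stretches of chromosomes, and an effect of MUC1-CD itself stays open and untested.

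Of 104 markers of host cell types at low signal on the 4 culture arrays, 59 (56.7%) were at least 2-fold higher in tumors, against 16.3% of all 3820 such genes and at most 30.8% in random sets. The share was highest for pericyte (7 of 8) and skeletal muscle markers (13 of 15). It was lowest for erythroid (2 of 6), keratinocyte (4 of 12) and lymphoid or granulocyte markers (8 of 22). RNA of mouse host cells may be the source of the higher markers, while induction in the rat cells was not tested. Among the most abundant, Acta1 was 5413 ± 625 and Hbb 3266 ± 60.7 in tumors (SD, n = 2). The 92 genes of the lower cholesterol, fatty acid and cell cycle lists had a median of -0.75 (log2) from culture to tumors. It lay below all random sets matched on signal (lowest -0.25). These lists were picked because they fell more than other genes, so the test cannot decide on dilution of rat RNA by host RNA. Whether host cells express these genes less than the matched genes was not tested. Dilution, growth setting and RNA preparation stay open for these lists, as they differ between the same arrays.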
